A study of Rattus norvegicus with 2 samples.

How the data were processed

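The series measured nuclear RNA in single nuclei from rat muscle. In the model, a piece of the tibialis anterior, a muscle at the front of the lower leg, was cut out of male Sprague Dawley rats (volumetric muscle loss). The gap was filled with adECM, fat tissue whose cells had been washed out by perfusion with detergents so that its matrix remained. The matrix had been seeded with adipose-derived stem cells (ASC) alone or with ASC and L6, a rat myoblast line. Muscle was taken at day 7. There was 1 library per group, called here the adECM+ASC and the adECM+ASC+L6 library. The labels say that muscle of both sides of each rat was removed, and how many rats or which sides entered each library is not given in the sources used here.

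Per the labels, nuclei were processed with a MobiCube 3′ kit and sequenced on a DNBSEQ-T7. The deposited matrices hold UMI counts, whole numbers per gene and nucleus barcode with no scaling, and the gene and barcode lists that the authors deposited with them hold names (unit: other). The submitters' processing notes name Seurat and mm10, a mouse build, without a version or role. The identifiers in the files are rat Ensembl genes, 32623 features in all, so the build used for counting is not given in the sources used here. Each matrix was matched to its library by the day and cell tags in its name. The tag for the adECM+ASC+L6 library abbreviates the group and does not spell it out. Another 2 matrices, whose names match neither library, are not used here. Genes are named by the symbols in the files where 1 feature carries the symbol. List members without such a symbol, among them Ttn, Myh1, Myh4, Col1a2 and Pecam1, were not matched here. Positions of named genes were taken by symbol from the RefSeq annotation of GRCr8, which need not be the build of the counts.

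The adECM+ASC matrix held 13323 barcodes and 25924462 UMIs, and the adECM+ASC+L6 matrix held 6329 barcodes and 13964830 UMIs. The lowest UMI number per barcode was 500 in the first and 1013 in the second, so the authors' barcode calling left different floors. The median share of mitochondrial UMIs was 1.15% and 3.78%. Nuclei were kept with at least 200 genes and at most 5% mitochondrial UMIs. These filters left 12950 and 4001 nuclei. The mitochondrial limit alone removed 373 barcodes (2.80%) of the first library and 2326 (36.8%) of the second. Scrublet (scanpy 1.11.5, expected rate 6%) marked 0 and 1 nuclei with its own threshold, which means that the caller did not work here, and doublets therefore remain. The 1 marked nucleus was removed, leaving 12950 and 4000.

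Both libraries were clustered together: counts scaled to 10000 per nucleus and log-transformed, 2000 variable genes, centring of each gene within its library, 30 principal components, 20 nearest neighbours, a shared-neighbour graph and Leiden clustering at resolution 0.8 (leidenalg 0.10.2). The 18 clusters were named with 20 marker lists. A cluster took the name of the list with the highest mean log2 fold over the other nuclei, where that mean was at least 1 and at least 3 markers were 2 times higher and seen in at least 5% of its nuclei. Clusters led by at least 5 cell cycle genes among their top 20 stayed unnamed. Names are written as "-like". They were rebuilt from markers here and need not match the authors' annotation.

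With 1 library per group there is no test between groups, and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals. Gene levels are CPM of UMIs summed over a class, that is, counts scaled to a common library total, with exact 95% Poisson intervals, and ratios carry exact conditional 95% intervals. All of these cover counting error only, not the spread between animals. For gene levels they also leave out the spread between nuclei of a class. Named classes, or the clusters of the muscle fibre-like class, with at least 100 nuclei in both libraries were compared, 8 in all. Unnamed clusters were not compared. Among them was a cluster of 812 and 326 nuclei led by muscle genes such as Ryr1 and Trim63. For 25 process lists, the median log2 CPM ratio over members with at least 10 UMIs (0.5 added to each sum) was placed among 10000 random lists matched on expression. Genes of 1 pathway vary together, so real lists lie outside the central 95% of random lists far more often than random genes do, and the percentile only describes these libraries. The genes named per class were the 8 highest and 8 lowest (3 each for smaller classes) by the ratio bound nearest 1. Eligible genes had at least 50 UMIs in the higher library and a UMI in at least 10% of the class's nuclei there. Their class CPM was also at least 25% of the gene's highest cluster, to limit free RNA of another class. That limit did not keep out every such gene: the macrophage genes C1qa and C1qc passed in fibroblast-like and myoblast-like nuclei. Identifier-like, mitochondrial and ribosomal protein genes were left out. Members of the lists and the labels' own markers are also named. Some genes that the rule or the lists name are not reported here. Shares of nuclei with a marker UMI were also taken after each nucleus was thinned to 1000 UMIs, which left out 4010 nuclei of the adECM+ASC library and 0 of the other.

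The muscle fibre-like class was compared as its 2 clusters, each with 8 genes each way, a choice made after seeing that the libraries filled them unequally. The lists followed through the alternatives were also chosen after their values were seen.

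The samples' groups, the comparisons, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Those alternatives were no doublet removal, at least 500 genes, no mitochondrial limit, Leiden resolutions of 0.4 and 1.5, each library clustered on its own, thinning, TMM scaling, no minimum for list members and class shares held equal. Added after seeing the data were a floor of 1000 UMIs in both libraries, that floor with no mitochondrial limit, removal of the highest 6% of doublet scores, no centring within library, and lists limited to members at 25% or more of their highest cluster level. The interval and list methods were run on simulated data with the endothelial-like class's depth. The simulated class sums were Poisson draws, the model that the intervals assume, without a spread between nuclei. The result therefore checks the calculation and not whether that model holds for these nuclei. Of 200 genes changed 2-fold, 89.5% had an interval on the right side of 1, and intervals of 96.2% of 8984 unchanged genes held the true ratio. Of 200 simulated unchanged lists of 12 genes, 2.0% lay outside the central 95%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.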

Results

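The series asked how muscle repaired by a seeded fat matrix differs when L6 myoblasts are added to the adipose-derived stem cells. Single-nucleus libraries of the adECM+ASC and the adECM+ASC+L6 group at day 7 were compared, 1 library each. After filtering, the adECM+ASC library held 12950 nuclei with a median of 1472 UMIs and 1045 genes, and the adECM+ASC+L6 library held 4000 nuclei with a median of 2034 UMIs and 1241.5 genes. There are no replicates, so every interval below is a 95% counting interval, and no difference was tested against the spread between animals.

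Muscle fibre-like nuclei made up a larger part of the adECM+ASC+L6 library, and T or NK cell-like nuclei a smaller part. Skeletal muscle fibre-like nuclei (Neb, Ckm, Ryr1, Trdn) were 1230 of 12950 nuclei, 9.50% (9.0 to 10.0), in the adECM+ASC library and 1025 of 4000, 25.6% (24.3 to 27.0), in the adECM+ASC+L6 library. T or NK cell-like nuclei (Cd3e, Cd247, Themis) were 9.90% (9.39 to 10.4) and 1.18% (0.865 to 1.56). Fibro-adipogenic progenitor or fibroblast-like nuclei were 9.10% (8.61 to 9.61) and 14.8% (13.7 to 15.9). Macrophage or monocyte-like nuclei were 16.6% (16.0 to 17.3) and 12.6% (11.6 to 13.7). Endothelial-like nuclei were 19.6% (18.9 to 20.3) and 17.9% (16.7 to 19.1). Muscle stem cell or myoblast-like nuclei were 3.77% (3.45 to 4.11) and 5.45% (4.77 to 6.20), and multinucleated giant cell or osteoclast-like nuclei (Ctsk, Atp6v0d2, Ocstamp) were 2.15% (1.91 to 2.42) and 4.13% (3.53 to 4.79). Vascular smooth muscle or pericyte-like nuclei were 2.10% and 2.53%, with overlapping intervals (1.86 to 2.36 and 2.06 to 3.06). Lymphatic endothelial-like nuclei, at 0.873% (0.720 to 1.05) and 0.95% (0.673 to 1.30), did not differ detectably at this depth, and dendritic cell-like nuclei were 1.67% (1.45 to 1.90) and 0.850% (0.589 to 1.19). Clusters left unnamed held 24.7% and 14.1% of the libraries. Among them was a cluster led by muscle genes such as Ryr1 and Trim63, at 6.27% and 8.15%, which is not counted as muscle fibre-like.

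These shares rest on filters that act unequally. The adECM+ASC+L6 matrix starts at 1013 UMIs and loses 36.8% of its barcodes to the mitochondrial limit, against 500 UMIs and 2.80% in the adECM+ASC matrix. With at least 1000 UMIs in both libraries and no mitochondrial limit, a setting chosen after the data were seen, muscle fibre-like nuclei were 13.1% (12.4 to 13.8) and 17.2% (16.2 to 18.1), and T or NK cell-like nuclei 5.84% (5.37 to 6.34) and 1.61% (1.32 to 1.95). Muscle stem cell or myoblast-like nuclei were then 2.57% and 2.53%. With no mitochondrial limit alone, endothelial-like nuclei were 19.6% and 24.3%, the reverse order. Giant cell-like nuclei were 2.00% and 0.625% when each library was clustered on its own, also the reverse order, and at resolution 0.4 no cluster took that name. Macrophage or monocyte-like nuclei were 16.2% and 9.17% with no doublet removal, and 18.6% and 16.9% when each library was clustered on its own.

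**Figure D1:**
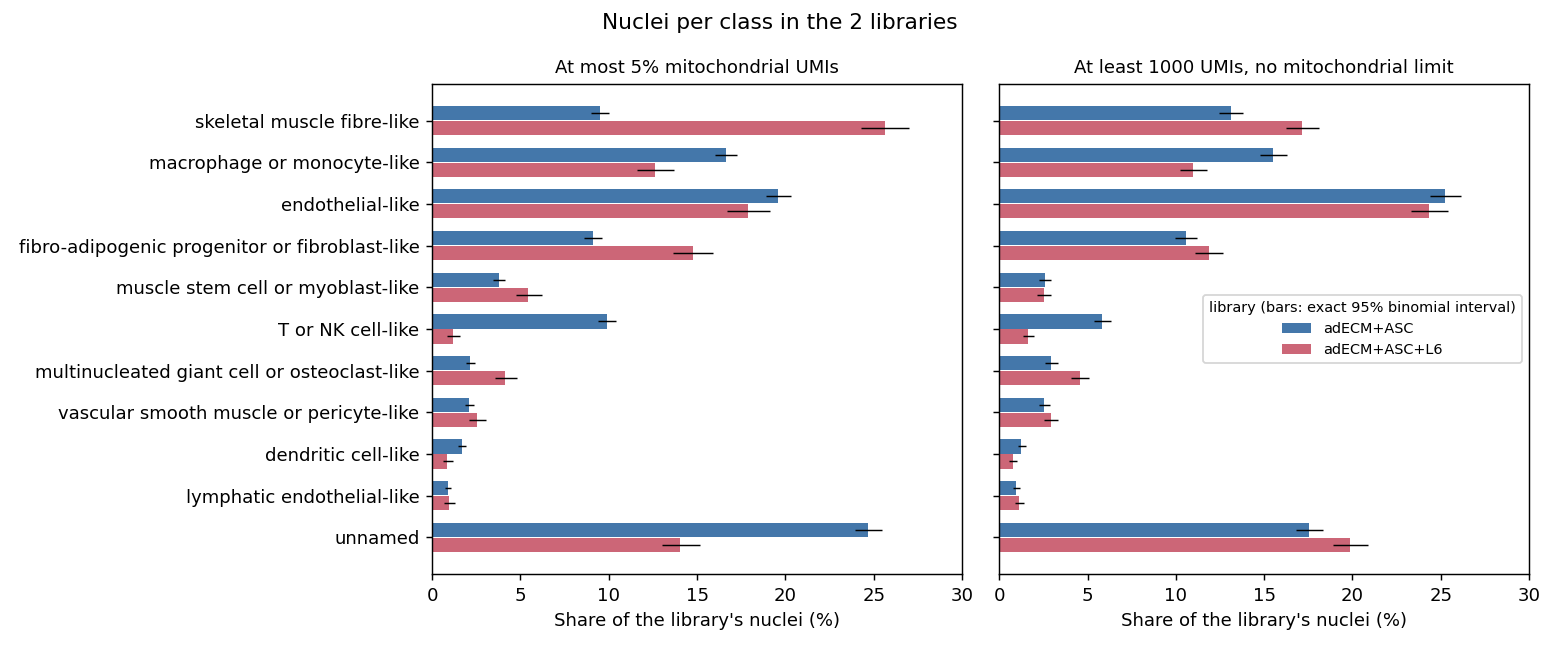
Share of each library's nuclei (percent, horizontal axis) in each named class for the adECM+ASC (blue) and adECM+ASC+L6 (red) libraries, with exact 95% binomial intervals as lines. Left, the main filters, where muscle fibre-like nuclei are 9.50% and 25.6%; right, at least 1000 UMIs and no mitochondrial limit, where they are 13.1% and 17.2%.

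The labels define cell types by 1 or 2 markers each. Ptprc, the pan-leukocyte antigen CD45, had a UMI in 60.7% (59.9 to 61.6) of adECM+ASC nuclei and 48.7% (47.2 to 50.3) of adECM+ASC+L6 nuclei. At 1000 UMIs per nucleus these shares were 46.2% and 35.1%. The share among endothelial-like nuclei, which should lack Ptprc, was 37.2% (median 2265.5 UMIs) and 28.1% (median 2299.5 UMIs), so much of the signal is background. Pdgfra, a receptor of fibro-adipogenic progenitors, was seen in 6.46% (6.04 to 6.89) and 9.35% (8.47 to 10.3), and in 2.48% and 2.93% of endothelial-like nuclei. Thinned to 1000 UMIs, the Pdgfra shares were 4.13% and 5.05%. Pax7, the transcription factor of muscle stem cells, was seen in 4.97% (4.60 to 5.35) and 5.75% (5.05 to 6.52), with 1.30% and 1.26% among endothelial-like nuclei. Thinned to 1000 UMIs, the Pax7 shares were 3.27% and 3.25%.

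Myh2 with Des, the labels' skeletal muscle definition, marked 17.4% (16.8 to 18.1) and 19.5% (18.3 to 20.7) of nuclei, and 10.2% and 5.03% of endothelial-like nuclei as background. After thinning it marked 9.87% and 9.0%. Eng without Ptprc, the labels' definition of adipose-derived stem cells, marked 12.3% (11.7 to 12.9) and 13.9% (12.8 to 15) of nuclei, 12.6% and 11.2% after thinning, and 5.37% and 4.20% of muscle fibre-like nuclei as background. The same definition, Eng without Ptprc, marked 42.5% and 53.5% of endothelial-like nuclei, and no cluster took the name adipose-derived stem cell. Myh11 with Acta2, contractile genes of vascular smooth muscle, marked 2.15% (1.91 to 2.42) and 1.85% (1.46 to 2.32), and 1.48% and 0.875% after thinning, against 0.511% and 0.198% of macrophage-like nuclei, whose medians were 1187.5 and 1436 UMIs. The order of the Myh2 with Des and the Eng shares turns after thinning and also with a floor of 1000 UMIs alone, so no order is read from them.

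Summed over all nuclei, Ptprc was at 992 CPM (980 to 1005) in the adECM+ASC library and 630 CPM (614 to 646) in the adECM+ASC+L6 library. Pdgfra was at 47.4 CPM (44.8 to 50.2) and 62.4 CPM (57.5 to 67.7), and Pax7 at 44.5 CPM (42.0 to 47.2) and 49.9 CPM (45.4 to 54.6). Myh11 was at 110 CPM (106 to 114) and 73.9 CPM (68.5 to 79.6), and Acta2 at 77.5 CPM (74.1 to 81.0) and 65.7 CPM (60.6 to 71.1). Des, which encodes the intermediate filament desmin, was at 168 CPM (163 to 173) and 145 CPM (137 to 153). With class shares held equal, the ratio of Ptprc was 0.888 in place of 0.635, and those of Myh2 and Eng changed side, from 1.17 to 0.836 and from 0.890 to 1.06. TMM scaling moved all whole-library log2 ratios up by 0.11.

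In endothelial-like nuclei (2538 and 716 nuclei, clusters 0 and 10), genes induced by interferons were lower in the adECM+ASC+L6 library. All 13 measured members of the interferon list were lower, with a median log2 ratio of -1.34 (-1.79 to -1.02), below each of the 10000 random lists. Markers of other cells were also lower in these nuclei, with medians of -1.18 for the T or NK cell list (9 of 10 lower) and -0.64 for the macrophage list (10 of 13 lower). So was the regenerating muscle fibre list, at -1.25 (9 of 9 lower), while the inflammatory macrophage list was higher. Free RNA or doublets of other cells can give such values. The test of free RNA given below covers only its lowest level over the classes, and doublets were not tested. The antiviral genes Mx2 and Rsad2 were 4.76 and 3.94 times lower, at 26.1 against 5.50 CPM and 34.7 against 8.80 CPM. Oas1a had 33 UMIs in the adECM+ASC library and 0 in the other. The genes furthest apart by the fixed rule belonged partly to the same response. Ubd, a ubiquitin-like modifier induced by interferon gamma, was 7.77 times lower (5.22 to 12.1), and Cxcl9, a chemokine that attracts T cells, 4.28 times lower (3.43 to 5.39). Slfn4, a schlafen family gene, was at 3809 CPM (3761 to 3858) and 984 CPM (939 to 1031), and Herc6, an interferon-induced ligase of ISG15, at 295 and 88.5 CPM. Slfn4 has near-identical family members with which it may share reads. Ubd lies on chromosome 20 (1390734 to 1392685) and Slfn4 on chromosome 10 (68492135 to 68515674) of GRCr8.

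Among the other lower genes in this class were Wipf3, an actin regulator (399 and 70.4 CPM), Akr1c15 (172 and 37.4 CPM), Galnt15 (89.6 and 21.4 CPM) and Ankrd55 (390 and 120 CPM). Higher in the adECM+ASC+L6 library were Mgat5, a glycosyltransferase that branches N-glycans (96.5 and 247 CPM), Slco2a1, a prostaglandin transporter (134 and 309 CPM), the proteases Adamts4 (41.5 and 103 CPM) and Adam12 (85.2 and 186 CPM), Lrp4 (39.1 and 123 CPM), Cbfa2t3 (75.7 and 163 CPM) and Mest (41.8 and 94.0 CPM). Fam111a, a protease gene on chromosome 1 (219065542 to 219081213), stood apart at 15.5 CPM (12.6 to 18.9) and 376 CPM (348 to 405), a ratio of 24.3 (19.6 to 30.4). It was also higher in giant cell-like nuclei (28.3 and 358 CPM) and smooth muscle-like nuclei (13.5 and 267 CPM).

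Vascular growth factor genes were split in endothelial-like nuclei. The list of angiogenic factors and receptors had a median of 0.34 (0.16 to 0.45), with 10 of 14 members higher in the adECM+ASC+L6 library, and of 0.25 with members at their own level. The endothelial markers, which share Kdr, Flt1 and Tek with it, were higher by a like amount (median 0.27, 7 of 8 higher). The VEGF receptors Kdr (276 and 372 CPM) and Flt1 (1218 and 1670 CPM) and the coreceptor Nrp1 (568 and 835 CPM) were higher. Angpt2, the antagonist of the Tek receptor, was at 227 CPM (215 to 239) and 74.2 CPM (62.2 to 87.9). Vegfa itself was at 66.0 and 185 CPM, but at only 2.71% of its highest cluster level in the first library, a level that free RNA of muscle fibres can give. All 18 measured cell cycle genes were higher, with a median of 0.46 (0.33 to 0.68), among them Top2a (24.5 and 36.8 CPM) and Bub1 (12.4 and 28.0 CPM). Only 4 cell cycle genes were at their own level here, with a median of 0.42 (0.24 to 0.77). A separate cycling cluster with endothelial genes held 0.788% and 1.83% of the libraries, and its free RNA can add to the others.

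**Figure D2:**
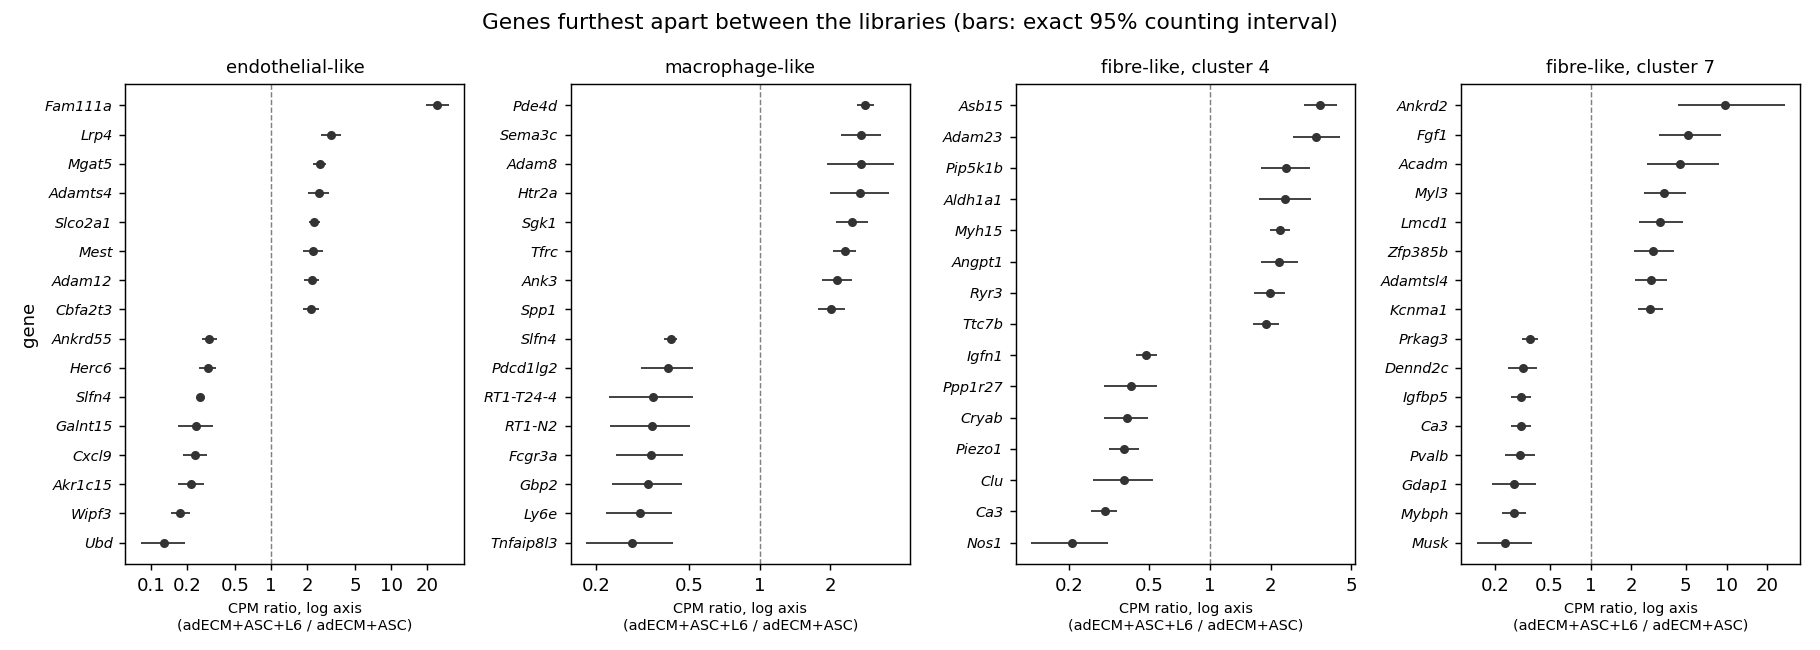
Ratio of CPM (adECM+ASC+L6 over adECM+ASC, horizontal log axis) for up to 8 highest and 8 lowest genes of the fixed rule in 4 classes or clusters, with exact 95% counting intervals as lines and a dashed line at 1. In endothelial-like nuclei Fam111a lies at 24.3 and Ubd at 0.129; in fibre-like cluster 7 Ankrd2 lies at 9.73.

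In macrophage or monocyte-like nuclei (2154 and 504), genes of antigen presentation were lower in the adECM+ASC+L6 library. All 6 measured MHC class II genes were lower, with a median of -0.85 (-1.03 to -0.67). MHC class II medians also lay below 0 in every other class or cluster compared, where free RNA can give such levels. The difference is therefore not shown to be particular to macrophages. In macrophage-like nuclei it was smaller with no doublet removal and with no mitochondrial limit, as given below. Ciita, the master regulator of the class, was at 380 CPM (358 to 403) and 173 CPM (145 to 204), and Cd74, the invariant chain, at 895 CPM (860 to 930) and 459 CPM (413 to 509). Of 11 measured interferon genes 10 were lower (median -0.57, -1.04 to -0.26). Markers of other cells were lower too, with medians of -1.04 for the T or NK cell list (8 of 9 lower) and -1.23 for the regenerating muscle fibre list (9 of 9 lower). By the fixed rule, Slfn4 (3478 and 1449 CPM), the interferon-induced Ly6e (175 and 53.8 CPM) and Gbp2 (142 and 47.5 CPM), the class I genes RT1-N2 (108 and 37.5 CPM) and RT1-T24-4 (96.4 and 33.8 CPM), the Fc receptor Fcgr3a (154 and 52.5 CPM), the PD-1 ligand Pdcd1lg2 (216 and 87.6 CPM) and Tnfaip8l3 (110 and 31.3 CPM) were lowest. RT1 and Gbp genes have close relatives in the genome with which they may share reads.

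Genes of lipid-handling macrophages were higher in the same nuclei. Of 12 measured members 10 were higher (median 0.27, 0.17 to 0.56), among them Trem2, a lipid-sensing receptor (39.2 and 76.3 CPM), Gpnmb (449 and 713 CPM), Lpl, lipoprotein lipase (49.2 and 100 CPM), and Spp1, osteopontin (214 and 434 CPM). Gpnmb and Spp1 also lead the giant cell-like cluster, whose border with these nuclei is unstable, and with no doublet removal the median was 0.10. Apoe was lower (725 and 535 CPM), as was Fabp4 (154 and 106 CPM). The repair macrophage list, with a median of 0.04, showed no such difference. The complement list was lower (median -0.62, -0.80 to -0.19), with C1qa at 142 and 72.6 CPM, but this depended on the setting: the median was -0.28 with no mitochondrial limit, -0.35 with members at their own level and -0.085 with no minimum count. The inflammatory macrophage list had a median of 0.32 (0.11 to 0.70): the neutrophil attractant Cxcl2 was at 7.63 and 40.0 CPM and Ccl3 at 48.9 and 138 CPM, while Il1b was at 203 and 169 CPM, with intervals that overlap (187 to 220 and 142 to 200). The same list was higher still in endothelial-like nuclei (0.88) and in fibre-like clusters 4 (0.75) and 7 (1.58), where such genes can be free RNA. Cxcl2 and Ccl3 also lead the neutrophil-like cluster that appears without a mitochondrial limit, so these values are not read as a macrophage state.

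The rule's highest genes in macrophage-like nuclei were Pde4d, a cAMP phosphodiesterase (451 and 1276 CPM), Sema3c (84.2 and 229 CPM), the kinase Sgk1 (137 and 342 CPM), the transferrin receptor Tfrc (259 and 599 CPM), the serotonin receptor Htr2a (39.5 and 106 CPM), Adam8 (30.8 and 83.8 CPM), Ank3 (166 and 355 CPM) and Spp1. Several depend on the border with the giant cell-like cluster, which shifted when the single marked doublet was kept: the ratio of Pde4d was then 1.59 in place of 2.83, of Sema3c 1.79 in place of 2.72, of Adam8 1.68 in place of 2.72, of Ank3 1.33 in place of 2.14 and of Spp1 1.19 in place of 2.03. Without a mitochondrial limit the ratio of Htr2a was 4.30 in place of 2.69.

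Muscle fibre-like nuclei fell into 2 clusters that the libraries filled unequally, cluster 4 with 1029 and 410 nuclei and cluster 7 with 201 and 615, so genes were compared within each. The unnamed cluster led by Ryr1 and Trim63 (812 and 326 nuclei) was left out of this comparison. In cluster 7, led by Pfkfb1, Ptpn3, Mybpc2 and Vegfa, genes of slow, oxidative fibres were higher in the adECM+ASC+L6 library and genes of fast fibres lower. Of 10 slow fibre genes 8 were higher (median 1.72, 1.39 to 2.25). The slow myosin heavy chain Myh7 had 2 UMIs against 81, a ratio of 16.0 (4.28 to 134), and Myl2 had 0 against 68. Myl3, a slow light chain, was at 71.0 CPM (50 to 97.9) and 246 CPM (220 to 274), and Myoz2 at 9.60 and 99.3 CPM. All 10 measured fast fibre genes were lower (median -0.69, -0.74 to -0.58): Myl1 was at 4774 and 2931 CPM, Actn3 at 1813 and 1023 CPM, and Pvalb, a calcium buffer of fast fibres, at 277 and 83.4 CPM. Of 14 oxidative metabolism genes 11 were higher (median 0.40, 0.23 to 0.68), with the fatty acid enzymes Acadm at 25 and 114 CPM and Hadha at 163 and 310 CPM. Vegfa was at 2439 CPM (2306 to 2577) and 4819 CPM (4702 to 4939).

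The rule's other genes in cluster 7 included the stretch-responsive Ankrd2 (11.5 and 112 CPM), Fgf1 (32.6 and 171 CPM), Lmcd1 (65.3 and 212 CPM), the potassium channel gene Kcnma1 (207 and 571 CPM), Adamtsl4 (129 and 356 CPM) and Zfp385b (82.6 and 239 CPM), all higher in the adECM+ASC+L6 library. Lower were Mybph (472 and 129 CPM), Ca3, carbonic anhydrase of muscle (638 and 196 CPM), Igfbp5 (655 and 202 CPM), Musk, the receptor kinase of the neuromuscular junction (99.9 and 23.5 CPM), Gdap1 (138 and 37.9 CPM), Dennd2c (286 and 90.9 CPM) and Prkag3, an AMP kinase subunit (858 and 310 CPM). With at least 1000 UMIs and no mitochondrial limit, the ratio of Igfbp5 was 0.530 in place of 0.309 and that of Musk 0.464 in place of 0.235. A cluster with 75.4% of its nuclei from 1 library may reflect that library as well as a fibre type.

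In cluster 4, led by Igfn1, Ankrd1 and Tp63, slow fibre genes were also higher (7 of 9, median 0.67, 0.53 to 1.04), with Tnni1 at 363 and 523 CPM and Casq2 at 380 and 590 CPM. The fast fibre list had a median of -0.05 there, but of -0.24 with at least 500 genes, -0.21 with no mitochondrial limit and -0.28 with at least 1000 UMIs. The rule's highest genes were Asb15 (62.8 and 222 CPM), Adam23 (31.9 and 107 CPM), the myosin gene Myh15 (193 and 430 CPM), Pip5k1b (35.9 and 85.1 CPM), the vessel-stabilising factor Angpt1 (62.2 and 137 CPM), Aldh1a1 (30.9 and 72.8 CPM), Ryr3 (99.0 and 195 CPM) and Ttc7b (136 and 258 CPM). Among the lowest were Nos1, neuronal nitric oxide synthase (94.7 and 19.6 CPM), Ca3 (546 and 164 CPM), the mechanosensitive channel Piezo1 (348 and 131 CPM), the chaperones Cryab (152 and 58.9 CPM) and Clu (87.0 and 32.7 CPM), Igfn1 (519 and 252 CPM) and Ppp1r27 (102 and 41.7 CPM). With at least 1000 UMIs in both libraries the ratio of Nos1 was 0.722 in place of 0.207, of Piezo1 0.595 in place of 0.377 and of Ryr3 1.19 in place of 1.97. In that setting 464 nuclei led by Ppp1r14c, Ca3, Igfn1 and Agbl1 formed an unnamed cluster of their own, so the lower Nos1, Ca3 and Igfn1 of cluster 4 may follow an unequal mixture of fibre nuclei within it. The cluster matched to cluster 4 there was led by genes such as Casq2, Myh15 and Tnni1. The same split appeared with at least 500 genes (424 nuclei apart) and with no mitochondrial limit (414 nuclei apart). The fast fibre medians of these settings are therefore of a different set of nuclei than that of cluster 4 at first. Whether the higher Casq2, Myh15 and Tnni1 of cluster 4 follow the same mixture was not tested.

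In fibroblast-like nuclei (1179 and 590), matrix genes of myofibroblasts were higher in the adECM+ASC+L6 library. Of 15 measured members of the myofibroblast and TGF-beta list 13 were higher (median 0.45, 0.28 to 0.55), with the matricellular genes Postn at 958 CPM (919 to 997) and 1687 CPM (1617 to 1758) and Tnc at 768 CPM (734 to 804) and 1448 CPM (1383 to 1514). Tgfb1 was lower, at 44.6 and 20.6 CPM. The collagens and matrix list had a median of -0.07. Interferon genes were lower (8 of 11, median -0.93, -1.08 to -0.47), as were the chemokines Cxcl9 (114 and 11.4 CPM) and Cxcl10 (88.0 and 19.8 CPM). C1qa (70.6 and 16.0 CPM) was also among the lowest. With members at their own level, the macrophage list was lower by as much as the interferon genes (median -0.97, 4 of 4 lower) and the complement list by more (-1.25), so fewer macrophage transcripts among these nuclei may be part of the difference. Asb15 (9.08 and 116 CPM), Ccdc103 (9.08 and 57.1 CPM) and Ttc7b (61.9 and 222 CPM) were highest. Asb15 and Ttc7b were also higher in fibre-like cluster 4, where Asb15 had its highest level in the adECM+ASC+L6 library. Asb15 was higher in myoblast-like nuclei too, so these differences are not particular to fibroblasts.

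Muscle stem cell or myoblast-like nuclei (488 and 218) had higher cell cycle genes in the adECM+ASC+L6 library (13 of 16, median 0.53, 0.23 to 0.86), with Mki67 at 32.7 CPM (23.3 to 44.5) and 61.5 CPM (42.6 to 86.0) and Brca1 at 22.1 and 101 CPM. The Mki67 intervals overlap. Only 4 cell cycle members were at their own level here (3 higher, median 0.70, 0.04 to 1.53). Medians at own level were also positive in endothelial-like (0.42), macrophage-like (0.35), giant cell-like (0.53) and smooth muscle-like nuclei (0.63). The difference is therefore not particular to myoblasts. Genes of embryonic myosins and fusion were slightly lower (9 of 11, median -0.32, -0.43 to -0.11; -0.64 with at least 1000 UMIs and no mitochondrial limit), including Myh3 at 1095 and 717 CPM and Myog at 203 and 150 CPM. The same list was lower in endothelial-like (-0.91) and macrophage-like nuclei (-1.12), where it is background, so background may add to this difference. When the class was clustered again, 228 of its nuclei formed a subcluster led by genes such as Casq2, Ankrd1, Myh3 and Tnni1. At resolution 1.5 the myoblast-like shares were 2.49% and 3.38%, and 297 nuclei took the name regenerating muscle fibre. The class therefore need not hold only stem cells and myoblasts. Asb15 (9.80 and 94.1 CPM) and Pkib (24.5 and 94.1 CPM) were higher, and Zswim3 (56 and 2 UMIs), C1qc (45.7 and 9.05 CPM) and Hspb8 (88.2 and 27.1 CPM) lower. C1qc is a macrophage gene, at 26.9% and 8.22% of its highest cluster level here, and 82 of these nuclei, 17.1% of them from the adECM+ASC+L6 library, formed a subcluster led by macrophage and endothelial genes such as Ctsc, Prkcb and Shank3, so its difference is not read as one of myoblasts.

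Giant cell-like nuclei of cluster 9 (279 and 165) had more Tfrc (160 and 584 CPM) and Car2, a carbonic anhydrase of osteoclasts (57.9 and 173 CPM), and less RT1-N2 (74.9 and 10.6 CPM) and Cd74 (424 and 138 CPM) in the adECM+ASC+L6 library. Their interferon list had a median of -0.66, but of 0.01 with only the 4 members at their own level. Smooth muscle or pericyte-like nuclei (272 and 101) had more of the complement gene C7 (103 and 339 CPM) and Errfi1 (727 and 1491 CPM) and less Gbp2 (120 and 18.1 CPM), Kcnab1 (933 and 339 CPM) and the class I gene RT1-CE10 (568 and 194 CPM). Their cell cycle list had a median of 0.47 (0.17 to 0.80). MHC class II medians lay below 0 in all 8 classes or clusters, between -1.57 and -0.47, but outside macrophage-like nuclei fewer than 4 members reached 25% of their highest cluster level, and free RNA of antigen-presenting cells can give such levels.

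**Figure D3:**
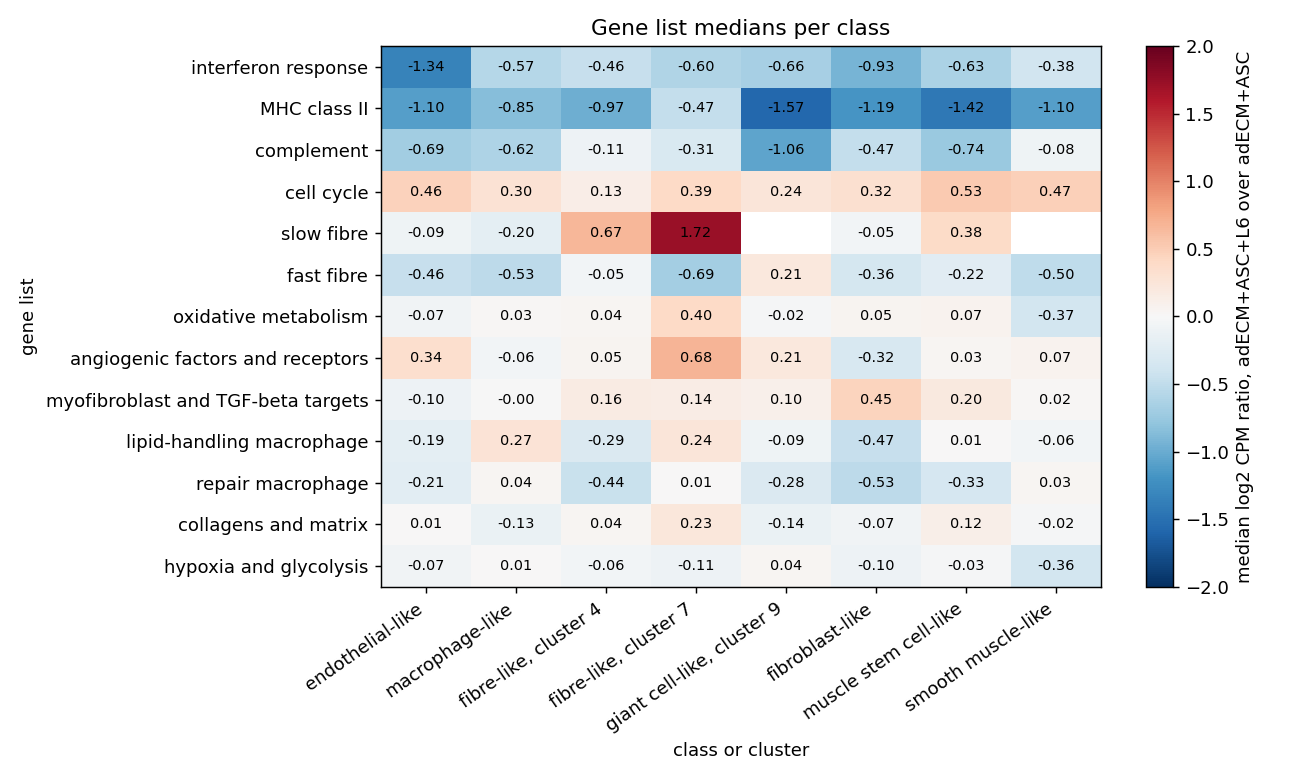
Median log2 CPM ratio (adECM+ASC+L6 over adECM+ASC, colour and printed value) of 13 gene lists in the 8 classes or clusters compared; blank cells had fewer than 4 members with at least 10 UMIs. The interferon row runs from -1.34 in endothelial-like to -0.38 in smooth muscle-like nuclei, and slow fibre genes reach 1.72 in cluster 7.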

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

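The tests of the UMI floor, the mitochondrial limit and share, the scaling and the levels of Fam111a over clusters, with the interval of its spread over nuclei, were chosen after the results were seen, as were the alternatives with at least 1000 UMIs and the lists limited to members at their own level.

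A small population that took a name only in some settings is not used in the comparisons. With no mitochondrial limit, a cluster led by Cxcl3, Cxcl2, Ccl3 and S100a9 took the name neutrophil, with 64 of 6325 nuclei of the adECM+ASC+L6 library, 1.01% (0.780 to 1.29), where 3 nuclei would be 0.0474%. In the adECM+ASC library it held 22 of 13322 nuclei. With the main settings no cluster took that name. With the limit kept, 19 nuclei of the adECM+ASC and 27 of the adECM+ASC+L6 library took it without centring, and 0 and 25 when each library was clustered on its own.

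The lipid-handling macrophage list, limited to members at their own level, went in opposite directions between classes. Its median was 0.38 in macrophage-like nuclei, -0.36 in endothelial-like, -0.62 in fibroblast-like and -0.76 in smooth muscle-like nuclei. It was -0.09 in giant cell-like nuclei, whose border with the macrophage-like class is unstable, and 0.11 in myoblast-like nuclei. The difference between classes was not tested.

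Interferon genes were lower in endothelial-like nuclei of the adECM+ASC+L6 library, with a list median of -1.34. For free RNA from other nuclei, the lowest CPM of any class in its library was subtracted from each gene. The median was then -1.09 (-1.84 to -0.89), which argues against free RNA at that lowest level as the cause. Free RNA above that level and doublets would remain after the subtraction, so they stay open. The unequal UMI floor and mitochondrial limit were argued against by the setting with 1 floor and no limit, with a median of -1.38, the mitochondrial share by 507 nuclei per library matched on it, with -1.11 (-1.41 to -0.73), and scaling by TMM, with -1.31. A difference between animals or library preparations stays open, because there is 1 library per group. The smaller share of T cells, which make interferon gamma, moves with this pattern, but no biological explanation can be separated from the animal here.

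The share of muscle fibre-like nuclei was 16.1 points higher in the adECM+ASC+L6 library under the main filters. With at least 1000 UMIs and no mitochondrial limit the difference was 4.05 points, so the filters account for a large part. A further 1.87% and 1.5% of nuclei were named regenerating muscle fibre there. The rest exceeds its counting half-width of 1.17 points. By counting error alone, this argues against the filters as the whole cause, only for nuclei that took the fibre name. Another 1251 nuclei, led by muscle genes such as Ryr1, Actn3 and Trim63, stayed unnamed there and are not counted. Whether a difference remains over all muscle nuclei is therefore not settled. Myh2 with Des, the labels' muscle definition, went the other way in that setting, at 22.3% and 15.7% of nuclei. That marker share carries much background, and the direction of the remaining muscle difference depends on the definition used. Different amounts of intact muscle in the tissue taken stay open, since with 1 library per group they cannot be told apart from the graft, and the labels say that muscle of both sides was removed.

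Fam111a was higher in each of the 16 clusters with at least 30 nuclei in the adECM+ASC+L6 library. A minority of carrying nuclei, such as implanted cells, stays open. Among endothelial-like nuclei 41.8% had a Fam111a UMI, 0.718 of the share that an even spread gives against a median of 0.916, at percentile 4.84 (1.73 to 9.69) of 289 genes of like level, an interval that holds the bound of 2.5. Free RNA from 1 source was argued against: without the highest cluster, the cycling one at 855 CPM, levels still differed 8.33 times between cluster 0 (409 CPM) and cluster 4 (49.1 CPM). Cluster 0 and the cycling cluster both carry endothelial genes, so that contrast alone does not address an endothelial source. Outside them, giant cell-like cluster 9 was at 358 CPM (301 to 424), also above cluster 4 (37.5 to 63.2). A variant near the gene that differs between the animals may account for the pattern, and with 1 library per group it stays untested.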

How the results depend on the processing

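With 1 library per group, a gene ratio was called unmoved where it stayed within its 95% counting interval, and a list median or share difference where it moved by no more than the half-width of that interval. Of the values recomputed under the alternatives, 562 gene ratios, 185 list medians and 75 share differences stayed, while 76, 11 and 37 moved, and 2 gene ratios and 9 share differences turned direction. A turn was counted only where the difference exceeded its counting half-width at first, which that of Pax7 (0.785, half-width 0.826) did not. The Pax7 difference still changed sign in 4 settings, to -0.0162 with thinning and as given below. The interferon medians of endothelial-like, macrophage-like and fibroblast-like nuclei stayed in every setting. That of giant cell-like nuclei was not followed and changed sign with members at their own level (0.01). T or NK cell-like nuclei kept their direction in every setting. The smaller median UMI number per nucleus of the adECM+ASC library (1472 against 2034) limits what its shares of nuclei with a marker can show. Where not said otherwise the cause was not tested. Differences below are the adECM+ASC+L6 share minus the adECM+ASC share in points.

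Thinning to 1000 UMIs gave -1.36 for Eng without Ptprc and -0.866 for Myh2 with Des (both reversed) and 0.922 for Pdgfra. No doublet removal gave -7.01 for macrophage-like and 5.01 for giant cell-like nuclei, and an MHC class II median of -0.54 in macrophage-like nuclei. At least 500 genes gave -5.71 for macrophage-like, -3.47 for endothelial-like and -8.03 for T or NK cell-like nuclei, and a fast fibre median of -0.24 in cluster 4. No mitochondrial limit gave 9.36 for muscle fibre-like, 4.75 for endothelial-like (reversed), 3.01 for fibroblast-like and 0.370 for myoblast-like nuclei, 4.97 for Eng without Ptprc, -2.01 for Myh2 with Des (reversed) and -0.0902 for Pax7, with medians of -0.64 for MHC class II and -0.28 for complement in macrophage-like nuclei and -0.21 for fast fibre genes in cluster 4.

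Resolution 0.4 gave 18.7 for muscle fibre-like nuclei. Resolution 1.5 gave -6.59 for macrophage-like, 0.881 for myoblast-like and 4.28 for giant cell-like nuclei. Each library clustered on its own gave 6.49 for muscle fibre-like, -1.66 for macrophage-like, 2.92 for myoblast-like, -7.31 for T or NK cell-like and -1.38 for giant cell-like nuclei (reversed). There a further difference of 8.87 lay in nuclei named regenerating muscle fibre, a name that no cluster took at first, so the smaller value for muscle fibre-like nuclei is largely a change of name. TMM scaling gave ratios of 0.685 for Ptprc, 0.961 for Eng, 1.26 for Myh2 and 0.932 for Des over the whole library. Equal class shares gave 0.888 for Ptprc, 1.06 for Eng and 0.836 for Myh2 (both reversed), 0.763 for Des and 1.10 for Pdgfra, by construction through composition. With no minimum for list members the complement median in macrophage-like nuclei was -0.085.

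The next settings were chosen after seeing the data. No centring gave -5.43 for macrophage-like and 0.842 for myoblast-like nuclei, and removing the highest 6% of doublet scores -5.49 for macrophage-like nuclei. At least 1000 UMIs gave 14 for muscle fibre-like, -2.70 for macrophage-like, -7.70 for endothelial-like, 4.00 for fibroblast-like, 0.554 for myoblast-like and -4.39 for T or NK cell-like nuclei. It gave -1.08 for Eng without Ptprc and -2.55 for Myh2 with Des (both reversed), 1.45 for Pdgfra, -0.570 for Pax7 and -0.924 for Myh11 with Acta2, and a fast fibre median of -0.28 in cluster 4. That floor with no mitochondrial limit gave 4.05 for muscle fibre-like, 1.30 for fibroblast-like, -0.0386 for myoblast-like (reversed) and -4.23 for T or NK cell-like nuclei. It gave -6.67 for Myh2 with Des (reversed), 0.792 for Pdgfra, -1.40 for Pax7 (a change of sign) and -0.954 for Myh11 with Acta2. Its medians were -0.64 for MHC class II and -0.31 for complement in macrophage-like nuclei, -0.79 for fast fibre genes in cluster 7 and -0.64 for embryonic myosins in myoblast-like nuclei.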

Other observations

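The hypothesis about L6 myoblasts and its threshold were set before its result was seen.

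A cycling cluster, left unnamed because 7 cell cycle genes were among its top 20, carried endothelial genes (Cdh5, Kdr, Flt1) and held 0.788% (0.643 to 0.955) of the adECM+ASC and 1.83% (1.43 to 2.29) of the adECM+ASC+L6 library. A cluster led by Nos2, Il1b, Plac8 and Ccl3, with a single neutrophil marker (Csf3r), held 2.61% (2.34 to 2.90) and 1.35% (1.02 to 1.76). A cluster led by Nr4a3, Cd83 and Ly75 held 1.53% (1.32 to 1.76) and 0.450% (0.267 to 0.710). Cluster 10 of the endothelial-like class, led by the arterial genes Bmx, Sox17, Gja5 and Efnb2, held 2.29% (2.04 to 2.56) and 2.83% (2.33 to 3.39).

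The largest unnamed cluster, 12.8% of the adECM+ASC and 1.78% of the adECM+ASC+L6 library, had a median of 676 UMIs, under the floor of the second library. Another unnamed cluster (6.27% and 8.15%), led by muscle genes such as Ryr1 and Trim63, had a median doublet score of 0.137, against 0.0234 in cluster 7. The feature AABR07000398.1 took 1.97% of all UMIs in the adECM+ASC library and 4.80% in the other, and mitochondrial features took 1.38% and 4.87%.

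L6 myoblasts that persist as a group apart from the host might form a cluster of their own. The 706 myoblast-like nuclei, of which 30.9% came from the adECM+ASC+L6 library, were clustered again without centring. The highest share of that library in any of the 6 subclusters was 35.9% (21.2 to 52.8), in a cycling one led by Top2a and Mki67, below the 90% set in advance. L6 nuclei that resemble host nuclei, or lie in other clusters, would not be seen this way.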
